A study of Homo sapiens with 4 samples.

How the data were processed

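Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, in 4 libraries of SUM159, an established human triple-negative breast cancer cell line. Per the labels, the cells were grown as spheroids on low-attachment plates for 9 days, dissociated, and depleted of dead cells to at least 85% live cells. Each library was its own group: a non-targeting shRNA control (NTC), a SMARCA4 shRNA knockdown (KD1), the knockdown with SMARCA4 expressed again (KD1+SMARCA4), and the knockdown with the rescue vector alone (KD1+Vec). There was 1 library per group and hence no replicate error for any group.

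The data used here are one peak list of the series, with 1 line per peak. Per the submitters' processing notes, Bowtie2, MACS3 version 3.0, bedtools and deepTools were used with the build hg38. The role of each tool, the filters, the removal of duplicates, any shift of read ends for the transposase and any removal of excluded regions are not given in the sources used here. Per the file headers, each line gives the chromosome, start, end, length, summit position, pileup, −log10 of the p-value, fold enrichment and −log10 of the q-value. The pileup is a signal deposited by the authors as whole numbers of stacked fragments at the summit, with no scaling to library size stated. The fold enrichment is a ratio deposited by the authors, of the pileup to the background that the peak caller expected at that place. The deposited −log10 p-value and q-value are the authors' values for a single peak against that background, and the highest q in the list is 0.00948. The length equalled end minus start for every peak, so starts were read as counted from 0 and are printed counted from 1.

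No header or column of the list names a library. It was therefore treated as a list of the whole series, and the comparisons between NTC, KD1, KD1+SMARCA4 and KD1+Vec that were fixed before the data were examined were not run. Fold, pileup and q describe single peaks within this list and carry no replicate error. The depth of each library is unknown. Exact Clopper-Pearson 95% intervals of shares are given, and they cover counting error only.

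The background behind each peak was computed as the pileup plus 1, divided by the fold enrichment, minus 1. The Poisson p-value recomputed from pileup and background had a −log10 value within 0.0016 of the deposited one for all 110612 peaks where it could be computed (98.7%). Genes came from the NCBI gene table of GRCh38.p14, the assembly that hg38 names, with 19974 protein-coding genes on chromosomes 1 to 22 and X. The table gives gene spans without strand, so a transcription start could not be told from a gene end, and exons and introns were not resolved. Transcription starts inside a span were not resolved either. Some spans lay far from any peak, such as LOC124905359 at 271994 to 418005 on chromosome 15, whose first peak started at 17007459. Whether such positions belong to the chromosome itself was not checked, and these genes count as genes without a peak. Each nuclear peak was placed at a gene boundary (overlapping the 1 kb either side of either end of a protein-coding gene), otherwise inside a protein-coding gene, otherwise inside another gene (non-coding genes and pseudogenes), otherwise between genes. As a background, all peaks were moved by 1 Mb and placed again.

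The 15 gene lists were fixed before the data were examined and all 384 entries matched a symbol or an older name. A gene's value was its strongest boundary peak by fold. That peak could lie wholly outside the gene span, within 1 kb of an end. Genes of a list called strongest or leading below are ranked by fold. The expected background differed by place, with a median of 30.6 at gene boundaries and 9.23 between genes. A lower fold can therefore go with a higher pileup. A list's share of genes with a boundary peak, and its median fold with 0 for genes without one, were set against 10000 random lists of the same size, drawn from all protein-coding genes and matched on gene length in 10 classes. The plan had been to assign peaks to the nearest transcription start and to match on number of peaks and level, for a median log2 ratio between libraries; the share and fold measures replaced it after the columns of the list were seen. The position among them is given as a percentile, which describes this peak list and is no p-value. The rule fixed for named genes took SMARCA4, ARHGAP29 and RHOA, and ranked others by change between libraries. As no change could be computed, the 3 genes with the highest boundary fold in each list, the list members without any peak, and the 10 boundary peaks with the highest fold and the highest pileup were named instead, a rule set after the columns but before the values of genes were seen. Peaks within 1 Mb of long gene-free stretches, in runs of raised background or outermost on a chromosome were left out of the last 2 rankings. Other genes named below were chosen after their values were seen. Some genes and gene lists that these rules took are not reported here. The motif analysis that had been planned needs genome sequence and was not run.

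Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data on the 19974 genes: 100% of genes given a boundary peak were recovered, a planted list of 30 genes reached the 100th percentile, and 6 of 100 random lists lay outside the central 95%. Of 10 bins of the real list given a background 10 times higher, 10 were found and 0 others were called. This result and the 100% recovery followed from the rules and check the code only. The simulated peaks were placed at a gene boundary. A background 10 times higher always passes the limit of 5 times the lowest background. The rule for runs of consecutive peaks was not part of this test.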

Results

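The series profiled open chromatin in 4 spheroid cultures of SUM159 cells, to ask how accessibility depends on SMARCA4 (BRG1), an ATPase subunit of the SWI/SNF (BAF) chromatin remodelling complexes. The NTC, KD1, KD1+SMARCA4 and KD1+Vec groups held 1 library each. The peak list held 112068 peaks that did not overlap one another, of which 112066 were nuclear, and they covered 97.3 Mb. Peaks had a median width of 700 bp (interquartile range 463 to 1051), a median pileup of 69 fragments (40 to 149) and a median fold enrichment of 5.30 (3.55 to 7.87). The list names no library, so SMARCA4 accessibility per library was not analysed here, neither knockdown against control nor rescue against its vector was compared here, and no peak is described as gained or lost. The depth of the libraries is unknown. The lowest background that the peak caller assumed was 8.35 fragments, and the smallest pileup called was 20.

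Open chromatin was concentrated at the ends of protein-coding genes. Of the nuclear peaks, 14370 (12.8%, 95% interval 12.6 to 13.0) lay at a gene boundary, against 4.26% (4.14 to 4.38) when the same peaks were moved by 1 Mb. A further 38.5% lay inside protein-coding genes, 13.6% inside other genes and 35.1% between genes. By median, boundary peaks were the strongest and widest, with a median pileup of 250, a median fold of 7.35 and a median width of 1291 bp, compared with a pileup of 55, a fold of 4.71 and a width of 657 bp between genes. The highest single fold (33.1) and the greatest width (34263 bp) were found between genes. Placement by overlap also favours wide peaks at boundaries. With the peaks split by fold into 4 groups of equal size, the share at gene boundaries was 5.64% in the lowest group, 7.68% and 15.6% in the next ones, and 22.4% (21.9 to 22.9) in the highest.

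**Figure D1:**
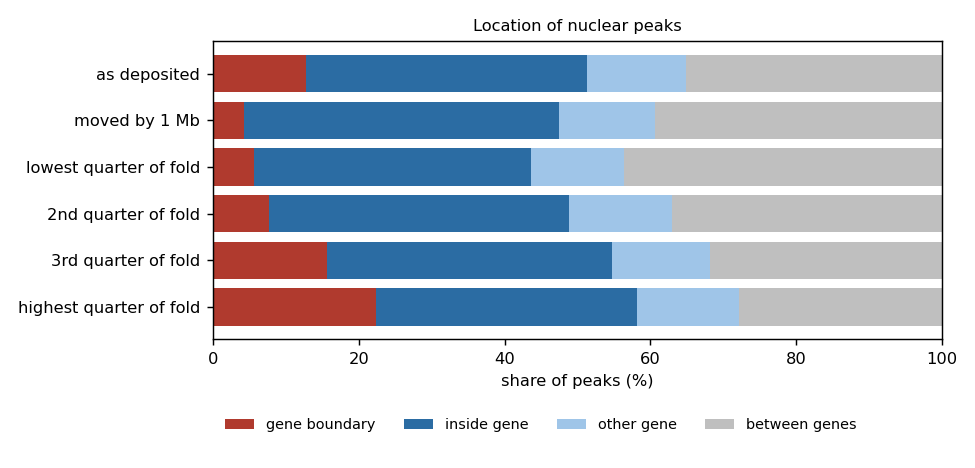
Share of nuclear peaks (x axis, percent) at protein-coding gene boundaries, inside protein-coding genes, inside other genes and between genes. The bars show the list as deposited, the same peaks moved by 1 Mb, and the 4 equal groups of peaks by fold enrichment; the boundary share is 12.8% as deposited, 4.26% after the move and 22.4% in the highest group.

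At the gene level, 14324 of 19974 protein-coding genes (71.7%, 71.1 to 72.3) had a peak within 1 kb of a boundary. Of these, 11853 had a peak at one end and 2471 at both ends. A total of 16849 genes (84.4%) had a peak at a boundary or anywhere inside, and 3125 (15.6%) had none.

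The 3 genes in the series title all had peaks at a boundary or inside, as did 84.4% of protein-coding genes. SMARCA4 (gene 6597, chromosome 19, 10961030 to 11062273) had 3 peaks. One lay across its lower-coordinate boundary at 10960199 to 10961819, with a pileup of 177 and a fold of 6.34. The strongest by fold lay inside the gene at 11035472 to 11036389, with a pileup of 249 and a fold of 12.1, above 96.7% of nuclear peaks. The third, at 11050585 to 11050869, was close to the calling limit, with a pileup of 23 and a fold of 2.57. ARHGAP29 encodes a GTPase-activating protein for RhoA. Its gene (9411, chromosome 1, 94168905 to 94314592) had 5 peaks, all inside the annotated span and none at a boundary. Transcription starts inside the span were not resolved, so the lack of a boundary peak does not mean that no start was open. The strongest peak lay at 94236336 to 94238002, with a pileup of 413 (above 96.5% of nuclear peaks) and a fold of 10.5. Peaks at 94246711 to 94248187 and at 94258672 to 94259519 had folds of 10.4 and 10.1, and the remaining pair near 94295915 and 94299860 had folds of 6.08 and 4.64. RHOA, a small GTPase that controls actin contractility, spans 49359145 to 49411976 on chromosome 3 (gene 387). Peaks covered both of its boundaries, at 49357387 to 49359231 with a pileup of 515 and a fold of 9.30, and at 49411213 to 49413017 with a pileup of 350 and a fold of 6.38. The strongest RHOA peak by fold lay inside the gene at 49377570 to 49378834 (fold 11.1). Neighbouring genes can share a boundary peak, and a peak was not tied to 1 gene.

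**Figure D2:**
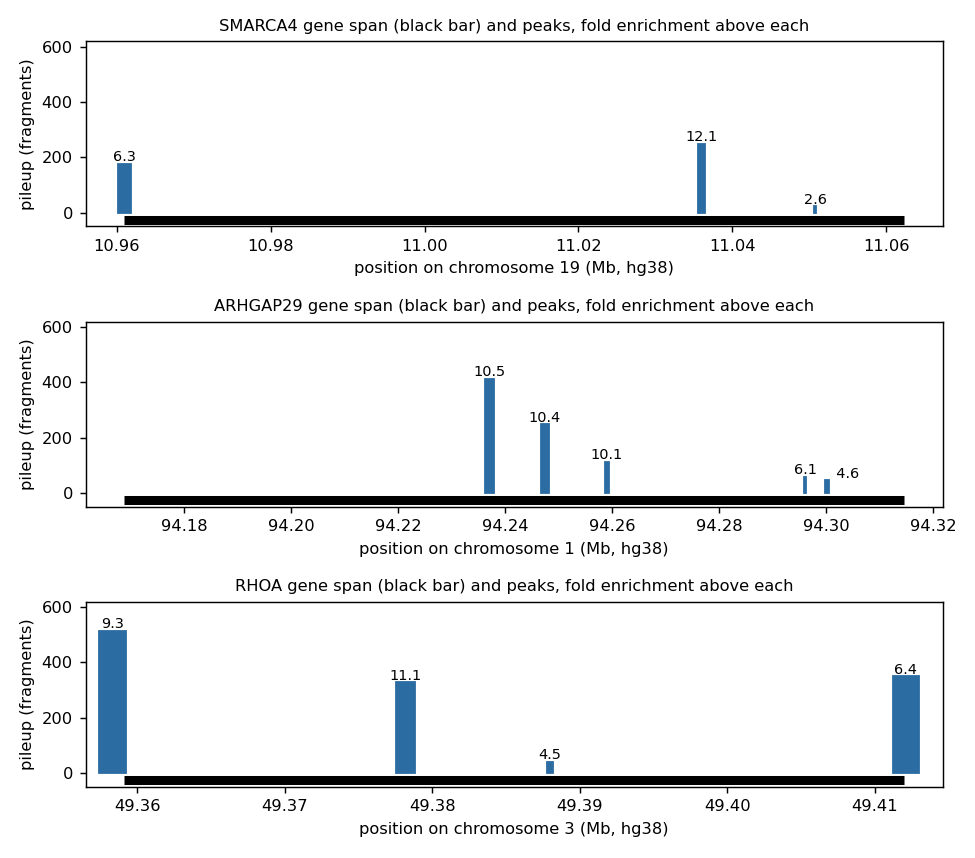
Peaks at SMARCA4, ARHGAP29 and RHOA, drawn to scale in hg38 coordinates (x axis, Mb) with the pileup in fragments as height (y axis) and the fold enrichment printed above each peak. Black bars are the gene spans, inside which transcription starts were not resolved. The ARHGAP29 peaks all lie inside its span, and RHOA has a peak at each end.

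Subunits of the SWI/SNF complexes had boundary peaks in nearly all cases. Of 28 subunits, 27 had one (96.4%, 81.7 to 99.9), which lay at the 99.6 percentile of random lists. With any peak in the gene all 28 had one, inside the range of random lists (percentile 93.6). The list was led by SS18L1 (pileup 352), PHF10 (fold 9.83) and SMARCD1 (fold 9.35). The SS18L1 and PHF10 peaks lay wholly outside the gene spans. ACTL6B, the neuronal subunit, had 1 peak inside the gene and none at a boundary. SMARCA2, the alternative ATPase, had a boundary peak with a pileup of 309 and a fold of 5.92. The median fold of the list, 7.45, lay inside the range of random lists, at the 74.4 percentile.

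Proliferation and housekeeping genes all had boundary peaks. All 30 G2-M and DNA replication genes had a boundary peak (lower limit 88.4%), with a median fold of 9.01 that lay at the 99.5 percentile of random lists. CCNB1 (cyclin B1, pileup 703, fold 12.6), MCM2 of the replicative helicase (fold 12.1) and CCNB2 (12.0) were the strongest. All 29 housekeeping genes had one as well, led by EMC7 (12.4) and VPS29 (11.3), with a median fold of 7.36 at the 84.5 percentile.

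Interferon response, cytokine, hypoxia and early response genes had boundary peaks more often than random lists. Housekeeping genes did too (percentile 99.995 by share), so this position does not mark these pathways as particular to these cells. Of 30 interferon response genes, 28 had a boundary peak (93.3%, 77.9 to 99.2), and their median fold of 9.13 was at the 99.97 percentile, the highest position of the 15 lists. The antiviral genes OAS2 (fold 12.4), OASL (11.8) and MX1 (11.2) led, and RSAD2 had no peak. Of 25 inflammatory cytokine genes, 22 had a boundary peak (88.0%, percentile 99.8), led by the NF-kappaB subunit RELB (12.8), the neutrophil chemokine CXCL8 (12.1) and CSF3 (9.82). IL6 had a pileup of 371 and a fold of 6.67, whereas CCL2, CXCL1 and CXCL5 had no peak. The hypoxia and glycolysis genes (27 of 28, percentile 99.9) were led by P4HA2 (13.1), PGK1 (9.99) and ENO2 (9.54). The AP-1 and early response genes (22 of 24, percentile 99.8, or 96.7 and inside the range with a 500 bp window) were led by BATF3 (10.8), DUSP5 (8.85) and EGR2 (6.91). The order by pileup differs: the DUSP5 peak had a pileup of 109, whereas JUN had a boundary peak with a pileup of 647 and a fold of 4.50. Of 27 YAP and TEAD targets, 25 had a boundary peak (percentile 99.5), led by AMOTL1 (11.9), FOXF2 (9.78) and LATS2 (8.91). The median folds of the last 3 lists were within the range of random lists (percentiles 32.2, 34.0 and 40.8), as was that of the cytokine genes (94.4). The peaks given here for OASL, RELB, CSF3, DUSP5 and FOXF2 lay wholly outside the gene spans.

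Epithelial and mesenchymal genes both lay within the range of random lists by share of genes with a boundary peak. Boundary peaks were found at 18 of 30 epithelial adhesion genes (60.0%, 40.6 to 77.3, percentile 5.89) and at 26 of 30 mesenchymal transition genes (86.7%, 69.3 to 96.2, percentile 96.4), and these intervals overlap; the difference was not tested. With any peak in the gene the counts were 26 of 30 and 27 of 30, while the epithelial list fell below the range with a 500 bp window (percentile 0.55) or with peaks above the median −log10 q (0.68). The mesenchymal regulators ZEB1 (fold 5.91), SNAI2 (6.42), TWIST1 (7.76) and ZEB2 (3.83) and the filament gene VIM (6.18) all had one, and ITGB3 (9.30) and TWIST2 (8.99) were among the strongest, while CDH11, POSTN and TAGLN had no peak. CDH11 lay in an interval of 3654 kb without any peak, so its lack of a peak is not particular to the gene. Of the epithelial genes, EPCAM (10.9), CLDN1 (10.7) and DSG2 (10.2) were the strongest. The only EPCAM peak, from 47387986, lay wholly outside the gene span, which ends at 47387020, and none was called inside the gene. CLDN3, CRB3, KRT19 and MARVELD3 had no peak, and CDH1 (E-cadherin) and GRHL2 had peaks inside the gene (9 and 14, the strongest with folds of 9.96 and 11.4) but none at a boundary. Of 35 matrix and integrin genes, 31 had a boundary peak (88.6%, percentile 94.6), led by COL5A2 (10.5), LAMA3 (9.47) and ITGAV (9.30), and ITGA4 had none in the gene.

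Mammary lineage and leukocyte genes lay within the range of random lists, and endothelial genes below it. Boundary peaks were present at 14 of 21 luminal genes (66.7%, percentile 24.4) and at 11 of 20 basal genes (55.0%, percentile 4.84). ERBB2 (fold 11.8), ELF5 (9.38) and ERBB3 (9.06) were the strongest luminal genes. PGR, the progesterone receptor, and KRT19 had no peak, and the oestrogen receptor gene ESR1 had a weak boundary peak (pileup 28, fold 3.10). PGR lay in an interval of 1550 kb without any peak, which also holds ARHGAP42, so its lack of a peak is not particular to the gene. Among basal genes, NGFR (10.8), OXTR (10.3) and MYLK (8.57) were the strongest, and KRT14, KRT6A, KRT6B and SOX10 had no peak. TP63 had 17 peaks inside the gene and none at a boundary. Leukocyte genes had 10 of 17 (58.8%, percentile 10.8), led by CD8A (11.3), CD3E (10.3) and SPI1 (10.1), and CD48, CD79A, LYZ and MS4A1 were among those without a peak. The leukocyte and endothelial lists had been fixed as a check of open chromatin foreign to this cell line. The leukocyte share lay between the luminal and basal shares, so a boundary peak did not separate leukocyte from mammary genes here. Endothelial genes had 3 of 10 (95% interval 6.67% to 65.2%), namely ESAM (8.85), ERG (7.83) and PECAM1 (3.17), which lay at the 0.265 percentile. CLDN5, KDR and TIE1 had no peak. The peaks given here for ERBB3, NGFR, ESAM and PECAM1 lay wholly outside the gene spans. With any peak in the gene, 7 of 10 endothelial genes had one and the list came inside the range (percentile 4.13). The basal list fell below the range with a 500 bp window (1.56), and the leukocyte list with peaks above the median −log10 q (2.45). Of the 15 lists, 8 had a share above the central 95% of random lists, 1 below and 6 within it.

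**Figure D3:**
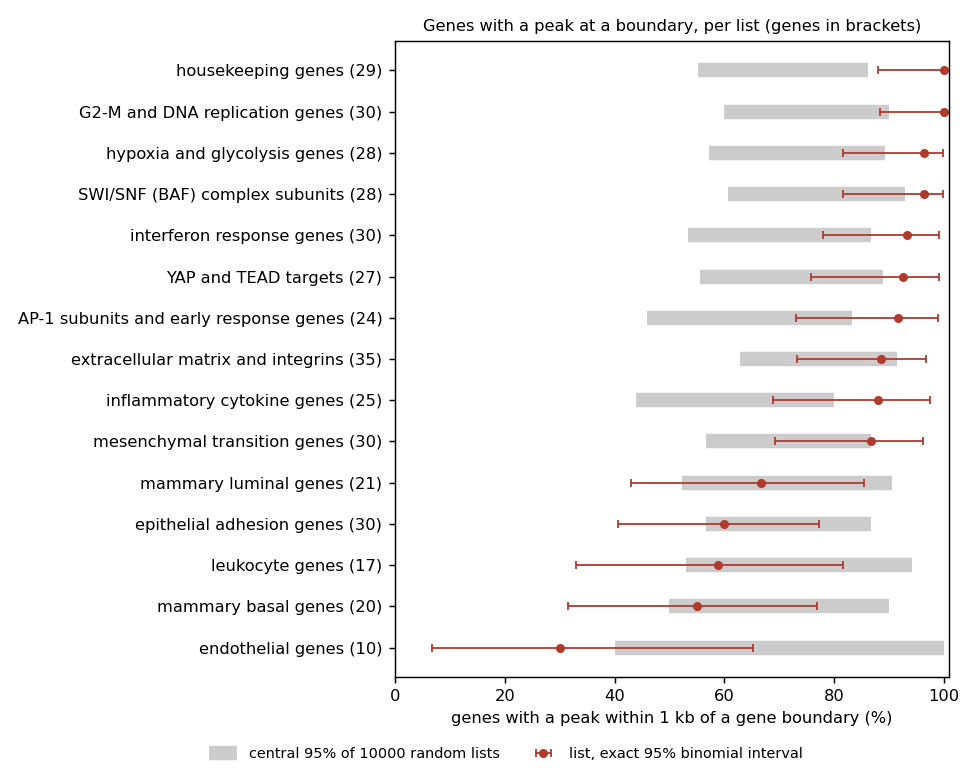
Percent of each list's genes with a peak within 1 kb of a gene boundary (x axis), for the 15 lists with the number of genes in brackets. Points are the list with its exact 95% binomial interval and grey bars the central 95% of 10000 random lists matched on gene length; the housekeeping and the G2-M lists are at 100% and the endothelial list, with 3 of 10 genes, is the lowest.

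The boundary peaks with the highest fold included 3 genes of the zinc finger and SCAN families, ZNF311 (fold 17.5), ZSCAN16 (16.8) and ZNF780B (16.4). IFTAP (17.2), the DNA repair enzyme ALKBH3 (16.7), CCDC22 (16.6), the mitochondrial threonyl-tRNA synthetase TARS2 (16.2), BTN3A1 (16.2), THG1L (16.2) and OXGR1 (16.1) completed the first 10. The OXGR1 peak lay wholly outside the gene span. The ranking by pileup held other genes. C2CD2L (1334), HINFP (1298), RPS25 (1227), H2AX (1092) and ZNF202 (1091), all on chromosome 11, were among its first 10. NBPF1 on chromosome 1 had the highest pileup (1536) but belongs to a family of near-identical copies, so its value is uncertain. C1QTNF3 (1104) and PDCD6 (1048) on chromosome 5 and EIF2AK3 (1044) on chromosome 2 were among them too. The expected background under these peaks ran from 102 at ZNF202 to 166 at C2CD2L. C2CD2L, HINFP, RPS25 and H2AX lay in a 500 kb bin whose lowest background was 1.49 times the lowest of the list. It was 1.81 times in the bin with ZNF202 and 1.22 times in that with PDCD6. These pileups are therefore not fully comparable with those elsewhere.

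The expected background was raised along whole regions of chromosomes 8 and 5. On chromosome 8, 196 consecutive peaks from 126926070 to 128202415, a span of 1276 kb with the protein-coding genes MYC and POU5F1B and non-coding genes such as PVT1, had a background of at least 5.61 times the lowest value and a median of 15.4 times. MYC had a peak at each boundary, at 127734048 to 127738449 with a pileup of 5894, a background of 1236 and a fold of 4.77, and at 127742951 to 127743820 with a pileup of 1667, a background of 300.1 and a fold of 5.54. On chromosome 5, 35 consecutive peaks from 2601330 to 2789075, around the homeobox gene IRX2, had a median background of 12.8 times the lowest value, and 48 from 3837502 to 4092730, with no protein-coding gene, had 11.3 times. In the 500 kb on either side, the median background equalled the lowest value for the chromosome 8 region (24 peaks) and for the chromosome 5 region from 3837502 (3 peaks), and was 1.82 times it for the region from 2601330 (5 peaks). A further 12 runs of 10 to 29 peaks lay on other chromosomes. Pileup is therefore not comparable between these regions and the rest of the genome.

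**Figure D4:**
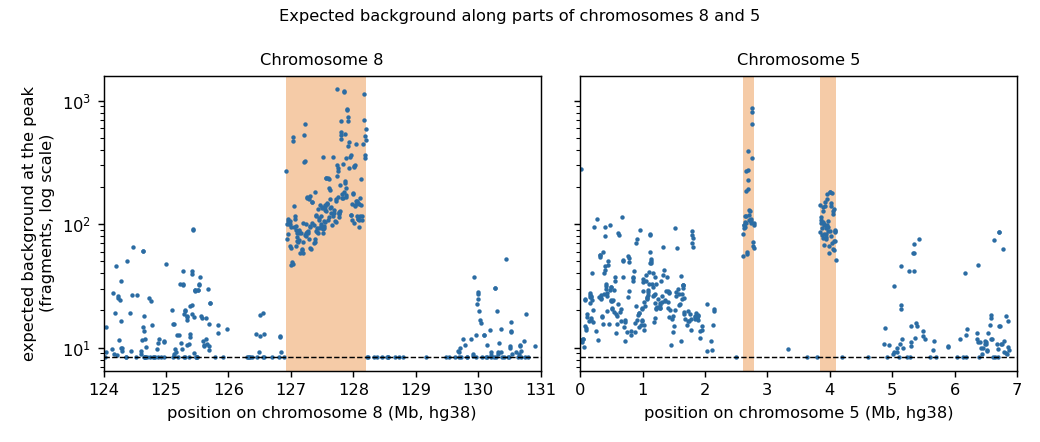
Expected background at each peak (y axis, fragments, log scale) along parts of chromosome 8 and chromosome 5 (x axis, Mb, hg38), 1 point per peak. The dashed line is the lowest background of the list, 8.35, and shading marks the runs of at least 10 consecutive peaks at or above 5 times that value; the medians inside the runs are 15.4 times the lowest value on chromosome 8 and 12.8 and 11.3 times on chromosome 5.

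Peaks were spread over all autosomes and X. Outside long gene-free stretches, the number of peaks per protein-coding gene ranged from 2.35 on chromosome 19 to 9.44 on chromosome 18, and chromosome 5 had 8.34, or 1.63 times the median chromosome for chromosome 18 and 1.44 times for chromosome 5. Per Mb, with all nuclear peaks counted, the order differed: chromosome 19 was the highest (66.6), with 35.7 on chromosome 18 and 44.5 on chromosome 5. The median fold per chromosome stayed between 4.70 on chromosome 21 and 5.67 on chromosome 6.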

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

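The test in this part was chosen after the result was seen. The mitochondrial chromosome, which no comparison used, had 2 peaks, with pileups of 9609 and 11760 and folds of 1.20 and 1.71. They are signal in data that no comparison above used.

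The file holds 1 peak list for 4 libraries. When the peaks were ordered by p, q fell at 0 steps, and 36422 peaks (32.5%) shared the same lowest background, within 0.001. The first is the test of, and argues against, a list merged from separate peak calls, since each call would bring its own adjustment of p. Whether the call was made on all libraries pooled or on 1 library stays open. If the shortest peak (265 bp) is the fragment length and the genome 2.9 Gb, the lowest background implies 91329898 fragments, and the depth of each library is unknown. No biological explanation was tested.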

How the results depend on the processing

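Keeping peaks with a −log10 q above the median (the stricter threshold) left 56034 peaks and raised the share of peaks at gene boundaries from 12.8% to 21.2%. That share was 11.5% with 500 bp, 15.4% with 2 kb and 13.5% without the gene-free stretches, and it did not leave its interval without the runs of raised background. The share of protein-coding genes with a boundary peak, 71.7%, became 67.8% with 500 bp, 77.0% with 2 kb, 64.0% with the stricter threshold and 84.4% with any peak in the gene. Ranked by median fold in place of share, 6 of the 8 lists above the range of random lists came inside it: SWI/SNF (percentile 74.4), YAP and TEAD targets (40.8), early response genes (34.0), hypoxia (32.2), cytokines (94.4) and housekeeping (84.5). With any peak in the gene, SWI/SNF (93.6) and the endothelial list (4.13) came inside, and with 500 bp the early response genes did (96.7). The epithelial list passed below the range with 500 bp (0.55) and with the stricter threshold (0.68), the basal list with 500 bp (1.56) and the leukocyte list with the stricter threshold (2.45). Bins with a raised lowest background were counted apart from the runs of consecutive peaks that define the regions of chromosomes 8 and 5. The rule for these runs was not varied. None of the raised bins covers the chromosome 5 region from 3837502. The 3 bins of raised background became 14 with bins 4 times smaller and 1 with bins 2 times larger, for which bin size sets the number by construction. For the others the cause was not tested. No list passed from one side of the range of random lists to the other, but some within it crossed the middle: by median fold, matrix and integrin genes went from 94.6 to 5.88 and mesenchymal genes from 96.4 to 27.9, with 2 kb basal genes went from 4.84 to 56.6, and with any peak in the gene epithelial genes went from 5.89 to 54.9 and luminal genes from 24.4 to 74.0. Only the stricter threshold for the number of peaks and the 500 bp and 2 kb windows for the share of peaks were fixed before the data were examined; all other alternatives, and the measures for genes, lists, background and chromosomes themselves, were chosen after seeing the data. The other normalizations, pseudocounts, fold thresholds, filters, peak overlaps and motif settings listed beforehand for changes between libraries were not run. No paired analysis was possible because each group has 1 library and the list names none. Without depths per library, the peaks near the smallest pileup of 20 limit what can be read from absence: a gene without a peak had no signal past the caller's threshold.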

Other observations

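The tests in this part, and the 14 gene families, were all chosen after the peak list had been seen. Gene families outside the fixed lists, grouped by symbol, differed widely in boundary peaks. Of 84 cytosolic ribosomal protein genes, 81 had one (96.4%, 95% interval 89.9 to 99.3, with a median of 64.3% in random lists matched on length), as did 37 of 40 proteasome subunit genes (92.5%, against 72.5%), 59 of 69 clustered histone genes (85.5%, against 47.8%) and 431 of 517 ZNF genes (83.4%, against 75.6%). Few genes had one in several other families: 30 of 392 olfactory receptor genes (7.65%, 5.22 to 10.7), 3 of 28 taste receptor genes, 3 of 45 defensin genes, 0 of 13 interferon alpha genes (upper limit 24.7%) and 19 of 94 keratin-associated protein genes had a boundary peak. Protocadherin clusters had 21 of 53 (39.6%, against 73.6%). Within the central 95% of random lists were collagens with 28 of 44 (63.6%, percentile 3.30), SOX genes 9 of 19 (47.4%, percentile 10.9), forkhead genes 37 of 52 (71.2%, percentile 91.2) and HOX genes 26 of 39 (66.7%, percentile 82.8). Among the HOX clusters, HOXC had 8 of 9 genes with a boundary peak, HOXB 7 of 10, HOXA 6 of 11 and HOXD 5 of 9. Clustered genes lie close together and share peaks, so they are not independent.

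Of 3351 protein-coding genes of at least 100 kb, 140 (4.18%) had no peak anywhere. The longest were CTNNA2 (1463 kb), DPP10 (1403 kb), LINGO2 (1276 kb) and CSMD3 (1214 kb), genes known for roles in neurons. The interval from 10941 to 3038597 on chromosome 3, which holds CHL1 and CNTN6, had no peak, nor had the interval from 4734317 to 7097192 on chromosome 2, which holds SOX11, CMPK2, RSAD2 and RNF144A. On chromosome 9, neither MTAP nor CDKN2A had a boundary peak, and each had a single peak inside, with a pileup of 35 and a fold of 3.85.

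The background was raised over whole regions of chromosomes 8 and 5, and no explanation tested was excluded or singled out. Extra copies of the DNA, a candidate explanation, cannot be told apart from the others: the smallest ratio of the median background inside a region to the 500 kb on both sides, pooled, was 7.06, but the regions were chosen for a raised background, and the 12 runs on other chromosomes chosen by the same rule had ratios of 2.29 to 29.1. Repeats collapsed in the assembly cannot be told apart without sequence: the longest of those runs held 29 peaks, on chromosome 21, against 196 on chromosome 8. Dense accessible chromatin cannot be told apart either: of equally long windows at least as densely covered by peaks, and over 1 Mb from gene-free stretches, only 0, 2 and 1 were found for the 3 regions, 0% of which reached the median background of the region. No biological explanation through the study's groups was tested.

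Gene-free stretches of at least 2 Mb held 5793 peaks (5.17% of nuclear peaks and 11.2% of the covered length), with a median pileup of 29 against 73 elsewhere. The pooled peak density was 4.15 times that of gene-free stretches of 0.5 to 1 Mb (33.4 against 8.04 per Mb). Single stretches ranged from 0 to 148 peaks per Mb. Lengths were not corrected for parts of the build without sequence, so these densities may be too low. The stretch from 480023 to 16024657 on chromosome 14, for example, held 0 peaks, and the first peak of that chromosome started at 16028961. A density of 0 there need not mean DNA poor in peaks. A high density restates the pattern, so it cannot decide whether these peaks are ordinary accessible sites of gene deserts. Reads from satellite repeats, which the build models in such stretches, may account for them: 90 of the 100 widest peaks lay there. Of the 100 peaks with the highest fold, 46 lay there, 16 were outermost on a chromosome and 3 were at a gene boundary. No biological explanation was tested.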
